A study of Mus musculus with 2 samples.

How the data were processed

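The series holds 2 libraries of spatial transcriptomics, in which RNA from a tissue section is captured on a grid of barcoded spots, each a small area that can hold several cells. Per the labels, 1 library came from nude mice with a flat implant and 1 from nude mice with a micropillar implant, the tissue was bone and the sections were formalin-fixed and paraffin-embedded. The deposited files hold raw UMI counts per gene and spot, whole numbers that were not normalised. Per the file headers the count matrices were made with Space Ranger 2.0.1, while the submitters' processing notes name Cell Ranger 7.2.0 and the mm10 genome build, and the labels' protocol names a directional mRNA kit. These sources do not agree on the upstream tool, and the aligner settings and probe set are not given in the sources used here. Spot positions and images were not used here, so no value depends on where a spot lay in the section.

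Both libraries list the same 19465 genes. Of a symbol on 2 rows (11 symbols) the row with more counts was used. Of the gene identifiers, 19451 matched the GENCODE M21 annotation of the same build, which gave the coordinates. Spots with at least 100 UMIs were kept, which left 2681 of 3161 spots and 2263345 UMIs in the flat library and 3064 of 3303 spots and 3173632 UMIs in the micropillar library. No doublet caller was run, since a spot is not a cell, and no cell-type makeup was estimated.

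With 1 library per group there is no replicate check. No test across libraries was made and no p-value is given. Counts were summed over spots and expressed as CPM, and the log2 ratio of micropillar over flat was taken with a pseudocount of 1 CPM. Intervals are 95% and cover counting error only, exact Poisson for a sum, exact Clopper-Pearson for a share or a ratio of counts without a pseudocount, and 1000 Poisson resamples for a list's median. A fold against a library with no UMI was taken against 3 counts in that library and is a lower bound. Before the data were examined, 37 gene lists were fixed, of which 12 concern bone, matrix, secreted factors, YAP/TAZ targets, the nuclear envelope and the actin cytoskeleton and 15 are markers of cell types, and 21 of their entries were not analysed here because the gene list of the files has no such symbol. A list's median over members with at least 5 CPM in 1 library was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

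Genes named section-wide were fixed by rule as the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in 1 library whose sign was the same with TMM scaling and with the mean of per-spot CPM. For each list the most abundant member and those with the highest and lowest ratio were taken. Some genes that these rules or the clustering select are not reported here. Within osteoblast-marker spots the 8 highest and 8 lowest were taken, leaving out the marker genes. Since 20 CPM is under 1 UMI in small sets of spots, a minimum of 10 UMIs in 1 library was added there after the depth was seen. The comparison within the matrix-gene region, its minimum of 30 UMIs for named genes and its alternatives were added after the data were seen.

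Spots of both libraries were clustered together without batch alignment, on counts scaled to 10000 per spot and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.6, with coordinates rounded so that the outcome does not depend on the processor. An earlier implementation with a standard neighbour search differed between processors, gave other region sizes and was replaced for that reason. Clusters are called regions and are described by their 5 leading genes. The matrix-gene region is the one with the highest Col1a2 level. Osteoblast-marker spots had at least 2 UMIs over 7 measured genes of an 8-gene marker set after each spot was thinned to 250 UMIs, and spots under that depth were left out.

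Scripts ran in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, umap-learn 0.5.12 and python-igraph 0.11.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for size factors. The procedure was tested on simulated data with 200 changed genes. Both simulated libraries were drawn with counting error alone from a shared pooled profile. Differences between sections beyond counting error were not simulated, so the shares recovered do not cover them. For the whole section, over 10695 genes, the interval excluded 0 in the right direction for 77.6% of genes changed 1.5-fold, 91.0% changed 2-fold and 100% changed 4-fold. For the matrix-gene region, over 1404 genes, these shares were 38.8%, 79.1% and 97.0%. Alternatives covered the scaling, the weight of each spot, the minimum of UMIs, the pseudocount, the clustering settings and the marker threshold.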

Results

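The data are UMI counts from 2 tissue sections of nude mice, 1 with a flat implant and 1 with an implant carrying micropillars, a patterned surface of small posts. The series title asks how microtopography bears on nuclear shape, the cells' secreted factors and bone regeneration. Each group had 1 library, so every comparison is between 2 libraries without replicates. Kept spots held a median of 602 UMIs and 485 genes in the flat library and 831 UMIs and 674.5 genes in the micropillar library.

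The sections were composed largely of spots with neural genes, and UMIs of the collagen and osteoblast lists lay mainly in 1 of 11 regions, region 3. Matrix protease and collagen processing genes were spread more widely. In the flat library the protease list had 497 UMIs in region 3 and 497 in region 1. Region 1, led by Slc17a7, Tafa1, Tbr1, Gm11549 and Slc30a3 and holding the glutamate transporter gene Slc17a7, took 23.7% of flat spots (95% interval 22.1 to 25.4) and 24.7% of micropillar spots (23.2 to 26.3). Region 4, with Lrrc10b, Adora2a, Ppp1r1b and Syndig1l among its leading genes, took 13.3% and 11.98%. Region 10, led by the neuropeptide genes Avp and Oxt, took 3.99% and 5.22%, and region 11, led by Ttr and Folr1, took 2.05% and 1.83%. Region 2, led by the astrocyte gene Gfap, took 13.9% and 17.0%.

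The matrix-gene region, region 3, was led by Mmp13, Ccn5, Elane, Atp6v0d2 and Comp and had the highest level of the type I collagen gene Col1a2. It held 412 flat spots, 15.4% (14.0 to 16.8), and 369 micropillar spots, 12.04% (10.9 to 13.2). Its spots were deeper in the micropillar library, with 456.9 UMIs per spot against 255.9, so that the region gave 4.66% of all UMIs in the flat library and 5.31% in the micropillar library. Region 5, led by the hair follicle keratin gene Krt25, took 5.67% and 7.51%, and region 6, led by Fcgbp and the epidermal gene Lor, took 7.57% and 4.34%. Region 7 had no abundant leading gene and took 4.66% and 6.01%. Regions 8 and 9 came mostly from 1 library and may be that library. Region 8, led by the muscle genes Tnni2, Myh2, Mb, Ckm and Myoz1, held 252 flat and 27 micropillar spots, and region 9 held 9 flat and 259 micropillar spots. Comp, a leading gene of region 3, itself differed between the libraries, so the shares of that region are given as values and not read as a difference. Region shares moved by more than their intervals under most clustering alternatives.

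**Figure D1:**
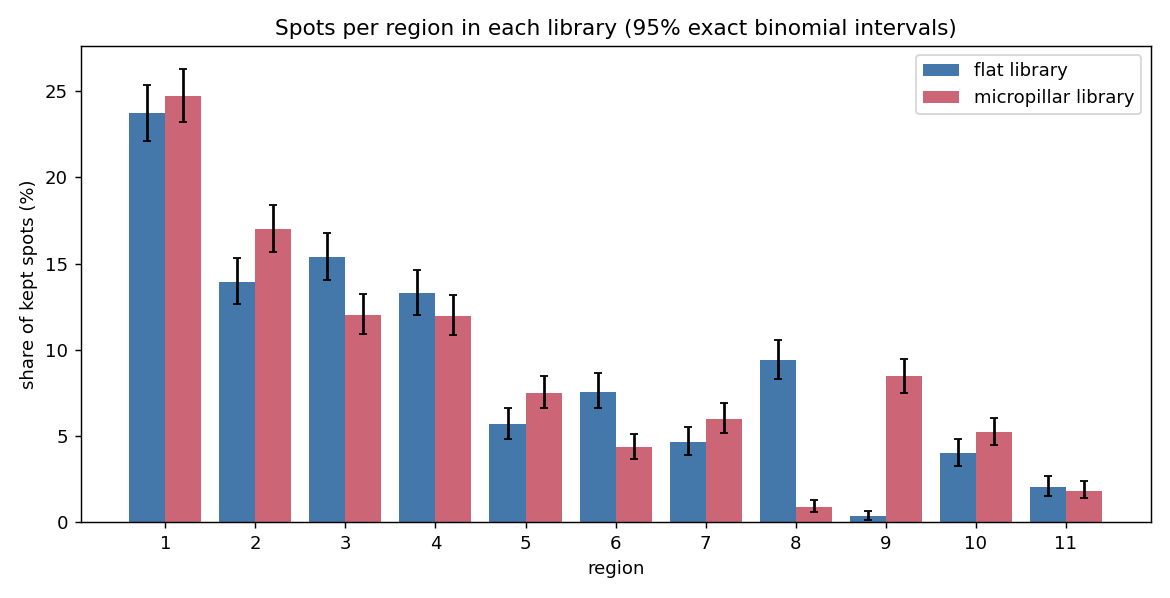
Share of kept spots (percent) in each of 11 regions in the flat and micropillar libraries, with 95% exact binomial intervals that cover counting error only. Region 8 held 9.40% of flat and 0.88% of micropillar spots, and region 9 held 0.34% and 8.45%.

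Over the whole section, genes of glandular secretions were found almost only in the micropillar library and skeletal muscle genes were lower there. Mucl2 had 1 UMI in the flat library and 1513 in the micropillar library, and Scgb1b2, a secretoglobin gene, had 1 and 1003. Gm1553 had 0 and 471 UMIs, at least 112-fold higher, Obp1a, an odorant-binding protein gene, 0 and 349, at least 83.0-fold higher, and Pip 0 and 77, at least 18.3-fold higher. Grid2ip, Krt6a, Gprc5d, Rgs16, Stk4, Itgb4 and Sema6d followed, with log2 ratios from 2.33 for Grid2ip to 1.41 for Sema6d. Among the lowest were the striated muscle genes Myoz1, Tnni2, Myh4, Mybpc2, Mb, Actn3, Myl1, Myh1, Acta1, Cmya5 and Tnnt3. Acta1, skeletal muscle actin, had 997 CPM in the flat library and 183 CPM in the micropillar library, a log2 ratio of -2.44 (-2.58 to -2.32), and Myoz1 had 121.5 and 12.9 CPM. In spots with at least 500 UMIs, which leaves out most muscle spots, Acta1 had a log2 ratio of 0.11. Among all 8082 genes with at least 20 CPM, 98.6% had a log2 ratio within 1 of 0, and the interquartile range was 0.37 against 0.20 from counting error alone.

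**Figure D2:**
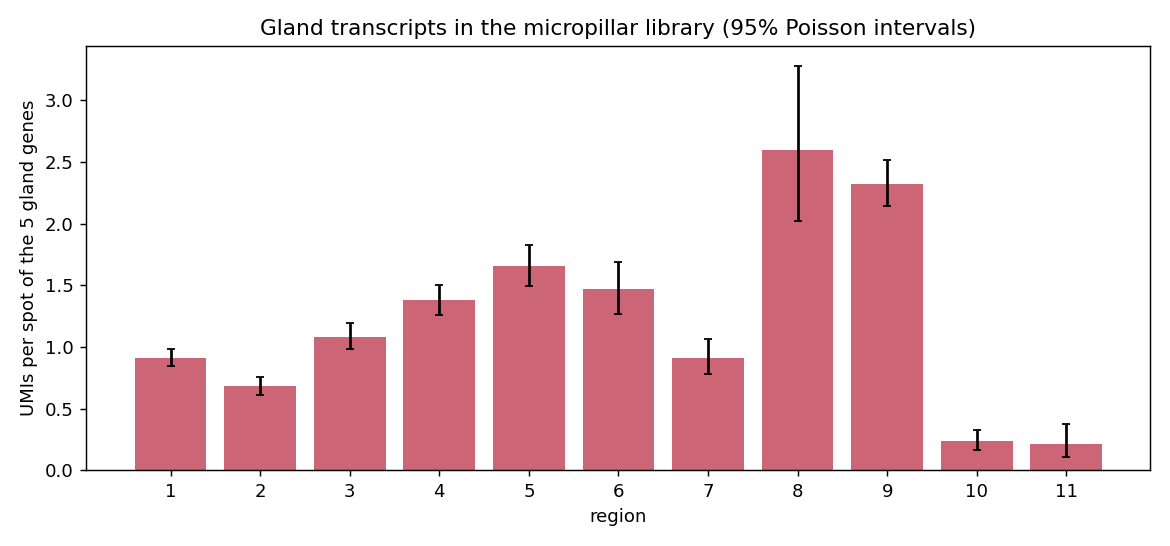
UMIs per spot summed over Mucl2, Scgb1b2, Gm1553, Obp1a and Pip in each region of the micropillar library, with 95% Poisson intervals. The values run from 0.21 in region 11 to 2.59 in region 8, and region 3 lies at 1.08.

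The collagen list was higher in the micropillar library by summed counts and lower when every spot weighed the same. Of 17 fibrillar and network collagens, 16 were higher by sums, with a median log2 ratio of 0.21 (0.14 to 0.29) at percentile 99.2 of random lists. With region 9 left out this median was 0.14, at percentile 94.5. The median was 1.22 in spots with at least 500 UMIs and -0.30 by the mean of per-spot CPM. Col1a2 (chromosome 6, 4504814 to 4541544, mm10) had 2286 and 2640 CPM in the flat and micropillar libraries, with the same change of direction. With equal weights Col1a2 was itself the list's median member, so its change is not separate from that of the list. Col8a1 had the highest ratio, 1.04 (0.35 to 1.95). The osteoblast list had 6 of 10 higher and a median of 0.17 (0.03 to 0.28), and -0.12 with equal weights. Its member Spp1, osteopontin, had 18.6 and 29.6 CPM. Collagen processing and crosslinking genes had 13 of 19 higher and a median of 0.15 (0.01 to 0.38), and -0.10 with equal weights. Matrix proteases and inhibitors had a median of 0.33 (-0.00 to 0.39), and -0.19 with equal weights. The non-collagen matrix list had 0.07 (-0.49 with equal weights, 1.04 in spots with at least 500 UMIs), cartilage 0.00, osteocyte 0.30 and osteoclast 0.18 (-0.17 with equal weights), each with an interval that included 0. Acp5, the osteoclast phosphatase gene, had 24.7 and 50.1 CPM, a log2 ratio of 0.99 (0.57 to 1.48), and Dmp1, an osteocyte matrix gene, had 25 and 10 UMIs.

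The lists closest to the series title had medians by summed counts over the section whose intervals included 0. Their UMIs came more from region 1 than from the matrix-gene region 3. In the flat library regions 1 and 3 held 670 and 175 UMIs of secreted growth factors and 1321 and 211 of YAP/TAZ targets. Nuclear envelope and lamina genes had 1139 and 212 there. The section-wide medians are thus not a reading of the matrix-gene region. Secreted growth factors had 13 of 26 higher and a median of -0.04 (-0.17 to 0.14), and -0.22 with equal weights, with Vegfb the most abundant at 125.0 and 130.1 CPM, Wnt5a highest at 18.1 and 33.1 CPM and Wnt16 lowest at 23 and 14 UMIs. YAP/TAZ targets, genes that respond to mechanical cues, had 9 of 19 higher and a median of -0.03 (-0.13 to 0.14), and -0.23 with equal weights. Nuclear envelope and lamina genes had 5 of 12 higher and a median of -0.16 (-0.23 to 0.04), at percentile 2.58 of random lists, and their summed counts had a log2 ratio of -0.13 (-0.21 to -0.06). Lmna, which encodes lamins A and C, had 233 and 241 CPM, and Banf1 had 234 and 177 CPM. Contractile actin cytoskeleton genes had a median of -0.04, and -0.29 (-0.33 to -0.25) for their summed counts, with Actb at 2734 and 2325 CPM.

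**Figure D3:**
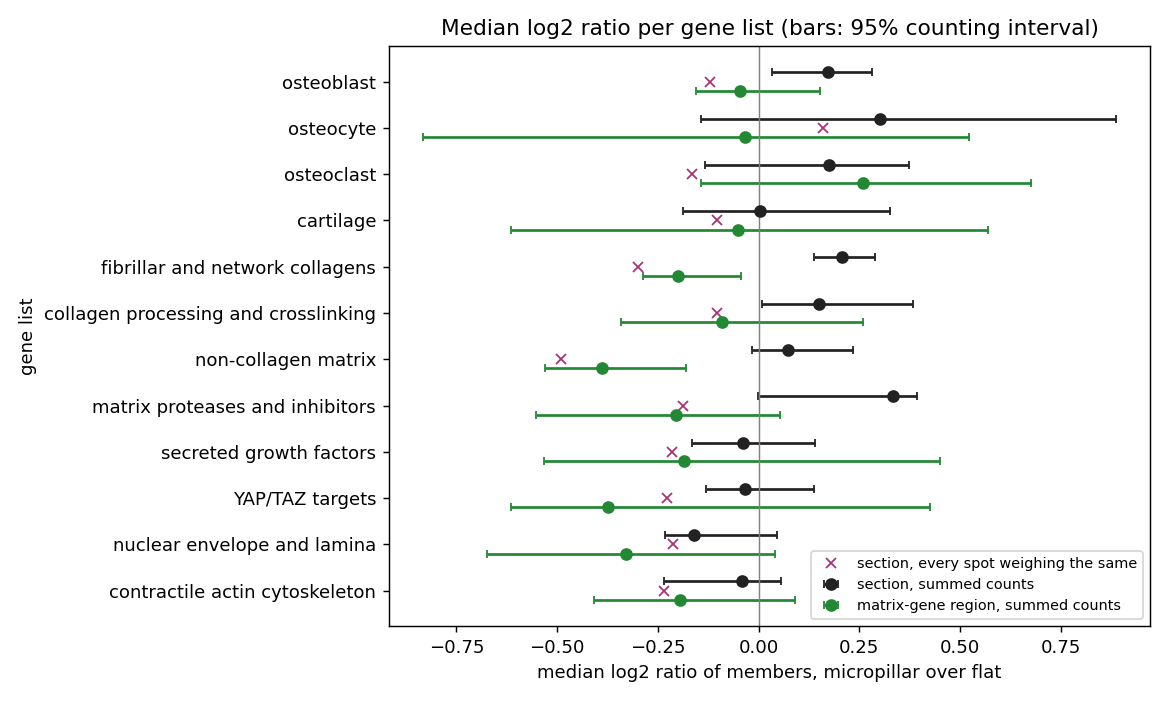
Median log2 ratio (micropillar over flat) of the members of 12 gene lists over the section and within the matrix-gene region, with 95% counting intervals, and crosses for the section when every spot weighs the same. The collagen list lies at 0.21 by summed counts, at -0.30 with equal weights and at -0.20 within the region.

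Within the matrix-gene region, Col1a2 was at nearly the same level in both libraries and several matrix genes were lower in the micropillar library. Col1a2 had 33356 and 32134 CPM in the flat and micropillar libraries, a log2 ratio of -0.05 (-0.12 to 0.01). The collagen list had 4 of 17 members higher and a median of -0.20 (-0.29 to -0.04), at percentile 20.7 of random lists, but 0.089 in the region's spots with at least 500 UMIs and -0.027 when spots were clustered without the bone and matrix lists. Non-collagen matrix genes had 4 of 20 higher and a median of -0.39 (-0.53 to -0.18), at percentile 0.68. In those same 2 settings this median was -0.033 and -0.14, both outside its interval. Fibronectin, Fn1, had a log2 ratio of -0.35 (-0.52 to -0.17), the thrombospondin gene Thbs4 -1.44 (-2.10 to -0.81) and Comp, a cartilage and tendon matrix gene, -1.36 (-1.72 to -1.01). Lower values were not particular to matrix genes. Medians were -0.39 for fibroblast, -0.60 for neutrophil, -0.73 for endothelium, -0.47 for keratinocyte and hair follicle and -0.39 for skeletal muscle genes, each with an interval below 0. The fibroblast list shares Dcn, Lum, Fbn1 and Col14a1 with the matrix lists. The neutrophil median was 1.33 at resolution 1.0 and 1.84 with clustering without the bone and matrix lists. Over the alternatives endothelium lay between -0.93 and -0.52 and keratinocyte and hair follicle between -0.76 and -0.17. Only oxidative phosphorylation had a median with an interval above 0. In the same micropillar spots the neural list had 5 of 8 members higher and a median of 0.40 (-0.08 to 1.05), with Snap25 at 256 and 652 CPM, and leaving genes that were higher in the most neural region out of the totals, which raises every remaining log2 ratio by about 0.20, put the collagen median at 0.0034 and the non-collagen matrix median at -0.19 (-0.32 to 0.02). Snap25 changed direction, to -0.26, when spots were clustered without the bone and matrix lists. TMM scaling moved the median of all genes in the region by 0.11.

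The osteoclast gene Acp5 was higher in the micropillar spots of the region, and the growth factor gene Gdf10 and the osteocyte gene Dmp1 were lower. Acp5 had 28 and 80 UMIs, a log2 ratio of 0.83 (0.20 to 1.51), Ctsk, the collagen-degrading cathepsin K, 0.26 (-0.21 to 0.74), and the osteoclast list had a median of 0.26 (-0.14 to 0.68). Of its 5 members 4 were higher, and Car2 was lower with an interval below 0. Car2 lay between -2.14 and -0.46 over the alternatives, and the mean of the list was -0.015. Dmp1 had 15 and 3 UMIs, a log2 ratio of -2.93 (-5.43 to -1.18), and Gdf10 had 19 and 5 UMIs, -2.56 (-4.38 to -1.13). These counting intervals make no allowance for genes being named for their ratio. Over 1114 genes of the region the interquartile range of log2 ratios was 0.79, against 0.45 from counting error alone. Their 5th and 95th percentiles were -0.75 and 1.68. The ratio of Acp5 thus lay inside the spread of genes there, while Dmp1 and Gdf10, on few UMIs, lay below it. The medians were -0.19 for growth factors, -0.37 for YAP/TAZ targets and -0.33 for nuclear envelope genes, where 0 of 7 were higher, and all 3 intervals included 0. The summed counts of nuclear envelope genes had a log2 ratio of -0.35 (-0.63 to -0.07), while the sums of the other 2 lists had intervals that included 0. In the region's spots with at least 500 UMIs growth factors were at 0.69 and YAP/TAZ targets at 0.65, and with clustering without the bone and matrix lists nuclear envelope genes were at 0.22. Lmna had 873 and 694 CPM. The osteoblast median was -0.05, osteocyte -0.03, cartilage -0.05, collagen processing -0.09, proteases -0.21 and actin cytoskeleton -0.20. Summed counts were at -0.90 (-1.19 to -0.61) for cartilage, -0.23 (-0.41 to -0.06) for proteases, -0.21 (-0.32 to -0.10) for actin cytoskeleton and -0.09 (-0.14 to -0.03) for osteoblast. Those of osteocyte and collagen processing had intervals that included 0. By the naming rule the highest were Mucl2, Scgb1b2, Gm1553, Obp1a, Scg5, Calb2, Nap1l5, Disp2, Sult4a1, Rnf112, Rtn1 and Nrsn2, mostly neural genes after the glandular ones, and the lowest were Avp, Ighj1, Car3, Hba-a2, Ftl1-ps1, Ace, Thbs4, Comp, Hist1h1d, Igha, Hbb-bs and Hbb-bt. Hba-a2, an alpha globin gene, had 4543 and 1524 CPM. In the 27 flat and 113 micropillar spots of the region with at least 500 UMIs, Comp, Acp5 and Fn1 had log2 ratios of 2.68, -0.032 and 0.023, each the opposite direction, while Dmp1 and Gdf10 were at -3.32 and -2.33. These spots held only 18487 flat and 96372 micropillar UMIs, so such ratios can rest on a few UMIs. For Dmp1 and Gdf10 they hold at most the few UMIs given above, so they are no check on those 2 genes.

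**Figure D4:**
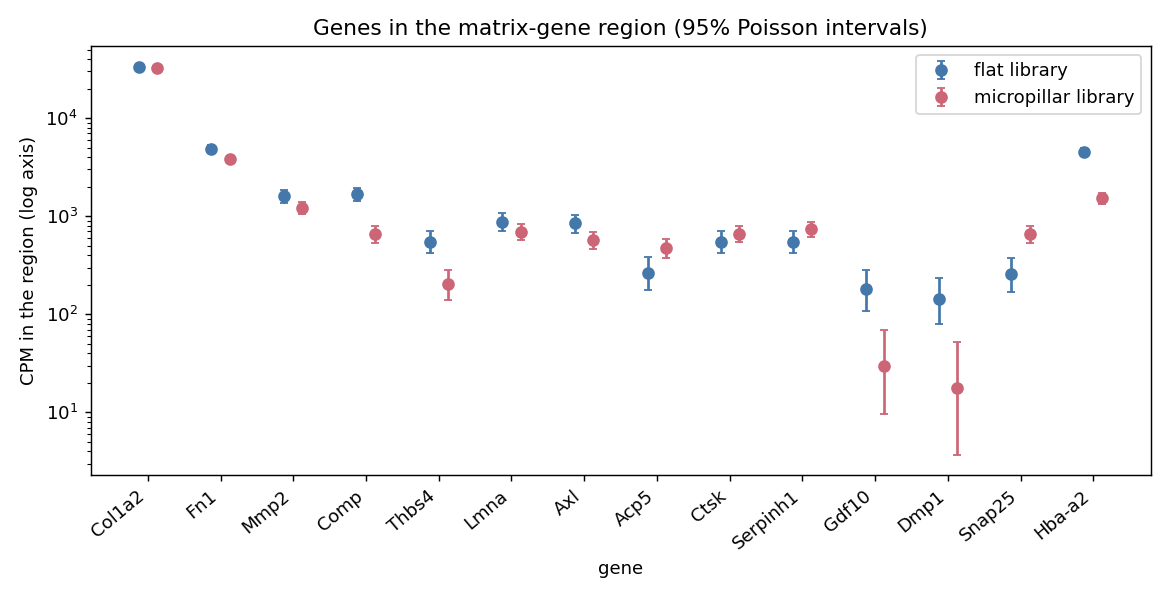
CPM on a log axis of 14 genes, chosen after their values were seen, in the matrix-gene region of the flat and micropillar libraries, with 95% Poisson intervals. Col1a2 lies at 33356 and 32134 CPM, and Dmp1 at 142 and 17.8 CPM.

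Osteoblast-marker spots were rare in both sections. After thinning, 20 of 2028 flat spots, 0.99% (0.60 to 1.52), and 20 of 2733 micropillar spots, 0.73% (0.45 to 1.13), were marker spots, and 653 flat and 331 micropillar spots were too shallow to enter. In the matrix-gene region 160 of 412 flat and 254 of 369 micropillar spots entered. The loss there was thus unequal, and the shares describe unlike parts of the 2 sections. Unthinned, the shares were 2.24% and 2.51%. In the matrix-gene region the shares were 8.75% (4.87 to 14.2) and 5.91% (3.34 to 9.55), in the muscle region 8 they were 3 of 32 and 2 of 16 spots, 9.38% (1.98 to 25.02) and 12.5% (1.55 to 38.3), and in region 1, where these genes should be lacking, 1 of 622 flat and 0 of 740 micropillar spots, which allows up to 0.41% if 3 counts are taken as the limit. The median UMIs before thinning were 332 and 470.5 in the matrix-gene region and 1887 and 1433 in region 1. The difference in share between the libraries was not detectable at this depth, and the comparison is limited further by the unequal loss of shallow spots.

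The marker spots summed to only 7381 UMIs in the flat library and 10874 in the micropillar library. There Comp had 5 and 31 UMIs, a log2 ratio of 2.07 (0.70 to 3.79), and Col6a3, a type VI collagen gene, 3 and 17. Nptn, Col2a1 and Surf4 had 2 UMIs each in the flat library, and Mucl2, Tchh and Krt34 had 0. The muscle gene Ckm had 26 and 2 UMIs, Hba-a2 had 53 and 22, and Hist1h1d, S100a9, Tcap, Vkorc1, Acta1 and Tnn were also lower. The collagen list had 6 of 7 members higher and a median of 0.30 (-0.04 to 0.52), and the osteoblast list without its marker genes 3 of 3 and 0.30 (-0.06 to 0.47). Both medians are the value of the same type I collagen gene, which is in both lists, so they are not separate results. With other marker thresholds these changed sign, to -0.18 for the osteoblast list at 1 UMI and to -0.019 for collagens and -0.60 for Col6a3 at 4 UMIs. Cartilage genes had 3 of 3 higher and a median of 1.76 (0.76 to 3.24), the value of Col2a1. Non-collagen matrix had 3 of 3 higher and 0.87 (0.16 to 2.19), and actin cytoskeleton 0 of 2 and -0.57 (-1.06 to -0.02). These medians lay at percentiles 84.2, 69.2 and 41.8 of random lists. Non-collagen matrix and Comp were lower within the matrix-gene region, at -0.39 and -1.36. Growth factor, YAP/TAZ, nuclear envelope and osteocyte lists had no member with 10 UMIs, so they could not be compared in these spots.

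Across spots, osteoblast-marker UMIs went with collagen genes in both libraries. Spearman's rho over spots, which are not independent, was 0.23 in the flat and 0.18 in the micropillar library for collagens, 0.24 and 0.21 for other osteoblast genes and 0.16 and 0.12 for cartilage genes. It was 0.03 and 0.01 for growth factors, 0.01 and 0.02 for YAP/TAZ targets, 0.04 and 0.04 for nuclear envelope genes and -0.10 and -0.10 for neural genes. The collagen and other osteoblast lists share a type I collagen gene, so their values are not separate results. UMIs of both lists lay mainly in the matrix-gene region, so values over all spots may largely restate that region. Within it, rho was 0.17 and 0.25 for collagens, 0.29 and 0.32 for other osteoblast genes and 0.22 and 0.34 for cartilage genes. Non-collagen matrix genes had -0.27 and -0.02 there, against 0.16 and 0.14 over all spots.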

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

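Spots with under 100 UMIs, which enter no main comparison, held collagen transcripts. With no minimum of UMIs per spot, section-wide medians by summed counts were 0.17 for collagens and 0.093 for osteoblast genes. Collagen genes made up 2.56% of the UMIs (2.36 to 2.77) in 480 such flat spots and 2.31% (2.08 to 2.56) in 239 such micropillar spots, against 0.55% and 0.63% in kept spots, and a count of 0 would allow 0.0131% and 0.0196%. Col1a2 alone had 281 and 197 UMIs there. The spots left out thus had a higher collagen share than the kept spots in both libraries.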

How the results depend on the processing

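The alternatives for the matrix-gene region, and clustering without the bone and matrix lists, were chosen after seeing the data. Of 1878 alternative values, 1531 stayed within the counting interval of the reported value, 304 moved outside it and 43 changed sign from a reported value whose interval excluded 0, which is called opposite direction here. A further 182 log2 ratios changed sign from a reported value whose interval included 0, which is called a change of sign here, and 51 of them are among the 304. The cause was not tested except where stated.

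With the mean of per-spot CPM, section-wide medians became -0.30 for collagens, -0.12 for osteoblast, -0.10 for collagen processing, -0.19 for macrophage and -0.21 for keratinocyte and hair follicle genes, all in the opposite direction as were Col1a2 at -0.30 and Snap25 at 0.14, a change of sign to -0.19 for proteases, -0.49 for non-collagen matrix and -0.17 for osteoclast, and -0.23 for YAP/TAZ targets, -0.22 for growth factors and -3.36 for skeletal muscle. This setting gives shallow spots the weight of deep ones. Under it Col1a2 is the median collagen, so the collagen and Col1a2 values are the same number.

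With at least 500 UMIs per spot, section-wide medians became 1.22 for collagens, 1.04 for non-collagen matrix, 0.70 for proteases, 0.65 for collagen processing, 0.51 for osteoblast, with a change of sign 0.22 for YAP/TAZ targets and 0.16 for actin cytoskeleton, and took the opposite direction for skeletal muscle (0.10), meninges (0.093), hypoxia and glycolysis (0.046), Acta1 (0.11), Actn3 (0.43), Cmya5 (0.047), Myh1 (0.20), Tnnt3 (0.35), Comp (1.59), Thbs4 (0.92), Lor (0.41) and Tpm2 (0.45). This minimum leaves 27 flat spots of the matrix-gene region with 18487 UMIs, and 113 micropillar spots with 96372 UMIs. There the medians became 0.089 for collagens and 0.20 for fibroblast, both in the opposite direction. So were Comp at 2.68, Acp5 at -0.032, Fn1 at 0.023 and Mmp2 at 0.26. The skeletal muscle median also took the opposite direction, at 5.41. That value is set by the pseudocount, since its median gene had no flat UMI there, and is not a fold. A change of sign was seen for cartilage at 2.68, which is the value of Comp. Collagen processing at 0.58, YAP/TAZ targets at 0.65, growth factors at 0.69, proteases at 0.16 and osteoclast at -0.35 also had a change of sign. Non-collagen matrix was at -0.033, actin cytoskeleton at -0.56 and nuclear envelope at -1.05. The matrix-gene region held 1.41% of flat and 5.23% of micropillar spots when these spots alone were clustered, and osteoblast-marker shares were 0.20% and 0.32%.

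Without spots rich in markers of other tissues, muscle genes took the opposite direction by the setting's construction, with 0.33 for the skeletal muscle list, 0.23 for Acta1, 0.33 for Actn3, 0.49 for Myh1, 0.13 for Myl1, 0.34 for Tnnt3 and 0.53 for Tpm2, and Lor was at 0.14. With a pseudocount of 5 CPM the skeletal muscle median was -2.01.

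In the matrix-gene region, leaving out genes higher in the most neural region raises every remaining log2 ratio by about 0.20 and gave 0.0034 for collagens, above 0 only through this change of scale, 0.16 for osteoblast, a change of sign, and -0.19 for non-collagen matrix. Clustering without the bone and matrix lists gave -0.027 for collagens and -0.14 for non-collagen matrix, a change of sign to 0.21 for osteoblast, 0.22 for nuclear envelope, -0.70 for neural and 0.32 for erythroid, which has 1 member there, and the opposite direction for neutrophil (1.84), Hbb-bt (0.17) and Snap25 (-0.26), with 13.3% of flat spots in the region. Resolution 1.0 gave the opposite direction for neutrophil (1.33), Hbb-bt (0.069) and Hist1h1d (0.059), with 12.5% of flat and 10.7% of micropillar spots. Resolution 0.3 gave 13.4% of micropillar spots, and 30 neighbours with 15 components gave 17.2% of flat spots.

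Osteoblast-marker shares in the flat and micropillar libraries were 2.61% and 3.59% with at least 1 thinned UMI, 0.30% and 0.26% with at least 4, and 2.24% and 2.51% unthinned. Within these spots TMM scaling gave 0.70 for both collagens and osteoblast, again the value of a type I collagen gene in both lists. At least 1 UMI gave a change of sign to -0.18 for osteoblast. At least 4 gave a change of sign to -1.19 for collagen processing and -0.019 for collagens, and the opposite direction for Col6a3 (-0.60) and Hba-a2 (0.048). These sets hold few UMIs, which limits each of these values.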

Other observations

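Outside bone and matrix, most lists lay near 0 over the section by summed counts, to which the values here refer. With every spot weighing the same, keratinocyte and hair follicle genes were at -0.21, macrophage -0.19, inflammatory cytokines -0.14, Wnt signalling 0.097, fibroblast -0.44, neutrophil -0.44, alternative activation -0.42, adipocyte -0.57 and pericyte and smooth muscle -0.38, and in spots with at least 500 UMIs alternative activation was at 1.61, fibroblast 1.08 and adipocyte 0.65. Keratinocyte and hair follicle genes had a median log2 ratio of 0.24 (0.10 to 0.40), with Krt14 at 752 and 1067 CPM in the flat and micropillar libraries, macrophage genes 0.23, Wnt signalling 0.32 (0.07 to 0.46), with Tcf7l2 at 16.3 and 44.7 CPM, and inflammatory cytokines 0.35 (-0.04 to 0.53). Skeletal muscle genes had -2.22, meninges -0.20, hypoxia and glycolysis -0.14, megakaryocyte -0.24, erythroid -0.23, B and plasma cell -0.11 and osteoclast-regulating factors -0.10. ER stress and secretion genes had 0.11, skeletal progenitor 0.13, pericyte and smooth muscle 0.05, endothelium 0.04, fibroblast 0.04, neutrophil 0.03, alternative activation 0.02, oxidative phosphorylation -0.00, Schwann and nerve -0.00, adipocyte -0.02, proliferation -0.05, neural -0.05 and immediate early and heat shock -0.06. Within the matrix-gene region, oxidative phosphorylation genes had 13 of 16 higher and a median of 0.51 (0.24 to 0.87), in spots where the summed neural list was also higher at 0.69 (0.39 to 1.00), though its median of 0.40 (-0.08 to 1.05) did not exclude 0, and only 2 of these genes, with a median of 1.18 (0.73 to 1.78), remained when genes higher in the most neural region were left out. When spots were clustered without the bone and matrix lists, the neural median was -0.70 and that of oxidative phosphorylation 0.35, so these lists did not move together in every setting. Adipocyte genes had -1.32 (-1.67 to -0.89).

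The tests on the glandular genes and the test with the matrix-gene region left out were chosen after the result was seen. The second definition in the test of neural transcripts and the comparison of glandular genes by CPM were also added after the first value had been seen. The test with the matrix-gene region left out replaced, after the values had been seen, a first test that had gone the other way, in which the log2 ratio of the region's share of UMIs, 0.19 (0.18 to 0.20), met the bound set for it as the cause.

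Mucl2, Scgb1b2, Gm1553, Obp1a and Pip gave 3413 UMIs in the micropillar library and 2 in the flat library. Expression in the tissue around the implant, taken as the matrix-gene region because the implant itself could not be located, cannot be told apart, since these UMIs per spot in the matrix-gene region were 0.97 times (0.87 to 1.08) those elsewhere while their CPM there was 2.37 times (2.13 to 2.63) that elsewhere. This excess is not particular to that region, since regions 5 and 8 had 2596 and 7124 CPM against its 2372. Gland UMIs hardly followed spot depth, with a Spearman's rho of 0.026 against 0.755 for Calm2, so their CPM rises where spots are shallow. Micropillar spots of the matrix-gene region had a median of 351 UMIs against 831 in all kept micropillar spots. Their CPM ratio is therefore not evidence of local expression. An even spread is argued against, since the lowest region had 0.092 of the UMIs per spot of the highest, among regions with at least 50 micropillar spots. Capture from glandular tissue in the section stays open, since the top 5% of spots held 1.46 times (1.37 to 1.56) the share of an even spread, and the bound of 1.5 lay inside that interval. RNA spread unevenly from a source outside the spots was not tested.

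Region 9, with 259 micropillar and 9 flat spots, had no abundant leading gene and held the deepest spot, with 19053 UMIs. Capture without regard to tissue may contribute and cannot be told apart from tissue, since olfactory, vomeronasal and taste receptor genes took 2.07 times (1.70 to 2.498) their share in other micropillar spots, between the bounds set before. Greater depth of its spots cannot be told apart either, since the number of genes at 200 UMIs, a median of 191 against 186, a ratio of 1.03, lies so near its ceiling of 200 that the test could not have gone the other way. No biological explanation was tested.

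The collagen list was higher over the section by sums but not within the matrix-gene region. A larger share of UMIs from that region is argued against as the whole cause, since with its spots left out the collagen median over the section was 0.50 (0.33 to 0.59), and 0.18 (0.08 to 0.32) with region 9 left out too. Region 9 gave 17.7 of 5548 collagen CPM in the flat and 837 of 6327 in the micropillar library, and with its spots alone left out the median was 0.14 (0.11 to 0.27). This lay at percentile 94.5 of random lists, whose 95% range reached 0.16, against percentile 99.2 with all regions. The median therefore did not stand out from random lists without region 9. Dilution by neural transcripts cannot be told apart from lower collagen, since leaving out 8115 genes higher in the most neural region moved the median by 0.20, while leaving out only the 4944 genes at least 2-fold higher there moved it by 0.11, in each case a change of scale alike for every remaining gene, and when spots were clustered without the bone and matrix lists Snap25 in the region changed direction to -0.26, the neural median was -0.70 and the collagen median was -0.027. An effect of the implant surface stays open and was not tested, since each surface had 1 library.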
